A study of Mus musculus with 14 samples.

How the data were processed

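Androgen receptor (AR) binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse ovarian granulosa cells, the cells that surround the oocyte in a follicle. Per the labels' protocols, 21-day-old mice received 5 IU equine chorionic gonadotropin (eCG), which makes follicles grow. They were killed 44 h later, before any ovulatory signal (0 h), or received 5 IU human chorionic gonadotropin (hCG), which stands in for the luteinizing hormone surge, and were killed 6 h after it. The 3 groups were wild type at 0 h (WT 0 h), wild type at 6 h (WT 6 h) and progesterone receptor (PGR) knockout at 6 h (KO 6 h), with 4 peak lists each. Per the labels, input DNA was pooled into 2 samples, input pool 1 for replicates 1 and 2 and input pool 2 for replicates 3 and 4. The inputs came with no processed files.

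Per the submitters' processing notes, reads were aligned with Bowtie2 2.4.5 to mm10 and peaks were called with MACS2, whose version and settings were not stated. The deposited lists were in MACS2's narrowPeak layout, and each was taken to come from 1 sample. The deposited fold enrichment was a ratio over the local background at the peak's summit. The deposited significance columns were −log10 p and −log10 q, and the deposited score was 10 times −log10 p, rounded down, as tested on the values. The lowest −log10 p in any list was 9.03 and the lowest −log10 q was 5.71. The form of the peak names differed between replicates 1 and 2 and replicates 3 and 4, the same division as the input pools. No read counts came with the lists, so the sequencing depth was unknown, and a site missing from a list may have been bound below the caller's threshold. Fold enrichment and −log10 p scale with depth, so they were used mainly to rank or filter peaks within a list. The median fold enrichment of a list was also among the 7 measures compared between groups and the 10 searched for lists far from their group.

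Positions were 1-based on mm10. Genes were taken from a RefSeq table of the GRCm38.p6 assembly with 21631 protein-coding genes, which gives each gene's start and end without strand or exons. A gene was counted as near a list's peaks when a summit lay inside it or within 50 kb of it. The planned promoter share needed the strand and was replaced by the percent of summits within 1 kb of either end of a protein-coding gene. No genome sequence was at hand, so the planned tests of 15 sequence motifs were not run.

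Peaks of the 12 lists that overlapped by at least 1 bp were merged into regions, and a region was held by a list when a peak of that list lay in it. Consensus regions of a group were the regions held by at least 2 of its 4 lists. For overlap between lists, each list was limited to its 1199 peaks with the highest −log10 p, the length of the shortest list, and the percent of these peaks that overlapped the other list's was averaged over both directions. The within-group minus between-group overlap was tested by a one-sided exact permutation test over the 35 splits of 8 lists. Values per list were compared by two-sided exact permutation tests over 70 arrangements, whose smallest p is 0.0286. Regions and genes were compared by Fisher's exact test, whose smallest p with 4 against 4 lists is also 0.0286, with Benjamini-Hochberg adjustment.

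For 21 gene lists, the log2 ratio of the share of a list's genes to the share of all protein-coding genes near each peak list was computed with 0.5 added to counts. It was compared between groups by the exact permutation test, with Benjamini-Hochberg adjustment over the 21 lists. Genes near consensus regions were tested against all other protein-coding genes by a one-sided Fisher's exact test, and against 10000 random lists matched on gene length. Of the symbols, 344 were matched and 2 were not. The groups, the main tests, the 21 gene lists and the rule for naming genes were fixed before the data were examined. By that rule up to 6 genes per gene list were named, with a summit in at least 3 of 4 lists of any group and taken by the largest difference in number of lists. In each direction of a comparison, 10 regions were named by the largest difference in number of lists and then by rank within lists. The 5 highest ranked regions of each group and Pgr, Ar and Runx1 were also named. The nearest gene is given for a region, which does not make it the region's target.

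The steps were tested on simulated lists built for the WT 6 h and WT 0 h comparison. In one case 200 regions were planted, divided equally between the groups, each in every list of its group and none of the other. All 200 were found among 242 called, against at most 59 in the other splits. Finding all 200 followed from how they were placed, so it tests only that the steps ran as meant. Lists with none planted gave 49 against at most 49. The overlap test missed the planted case (exact permutation p = 0.0571, and 0.0857 with none planted). In the simulated lists a peak's rank was drawn at random in each list, and the longest lists were simulated shorter than they were. This miss therefore says little about the overlap test on the real lists. The simulated counts also do not cover lists as unequal in length as the real ones. With peaks placed at random, 1 of the 21 gene lists, the RUNX genes, passed the enrichment test. A peak planted near every gene of the circadian clock list in one group gave an exact permutation p of 0.0286 but an adjusted p of 0.257. At least 12 of the 21 lists have to reach the smallest p before any passes an adjusted 0.05, so a count of 0 lists carries little information. In 6 checks against other tools, 0 differed. Alternatives were stricter peak thresholds, equal list lengths, other overlap rules, other distances to genes, exchange within replicate numbers or input pools, and leaving out each list in turn. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, matplotlib 3.10.9 and bedtools 2.31.1.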

Results

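The binding sites of AR were mapped by ChIP-seq in granulosa cells of growing follicles (WT 0 h), 6 h after an ovulatory dose of hCG (WT 6 h), and at the same time in mice without PGR, the progesterone receptor that the ovulatory signal induces (KO 6 h). There were 4 peak lists per group and 69867 peaks in all. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples. The WT 0 h lists of replicates 1 to 4 held 6197, 5083, 6499 and 19960 peaks. The WT 6 h lists held 1199, 3967, 7560 and 1809 peaks. The KO 6 h lists held 3198, 7158, 4359 and 2878 peaks. The number of reads behind each list was not given, and the lists hold no measure of PGR itself, so the knockout could not be checked in them.

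**Figure D1:**
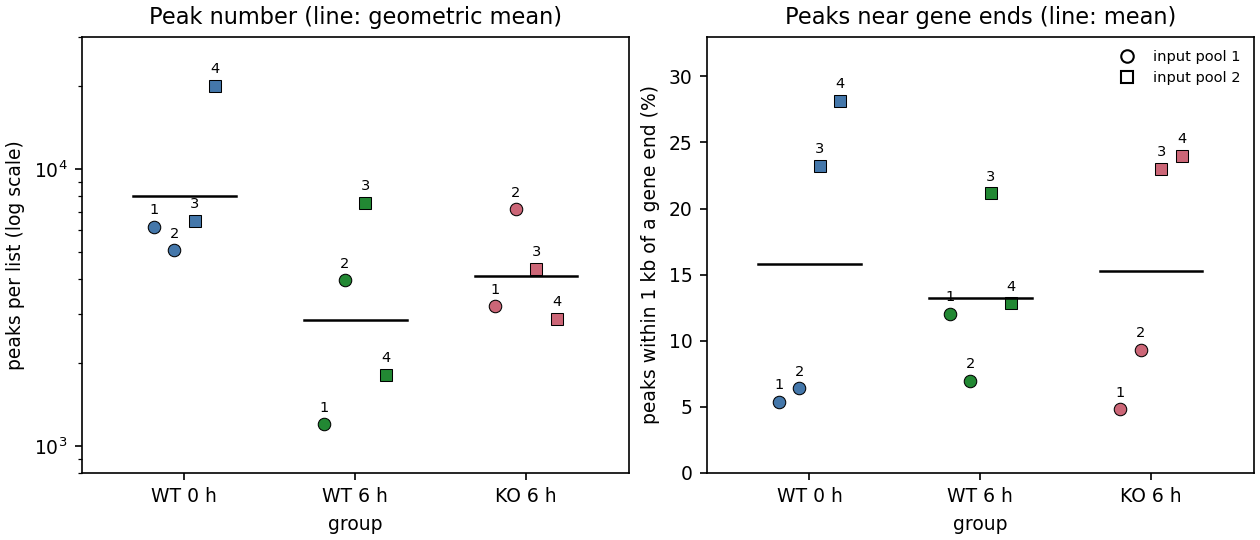
Peaks per list on a log scale (left, line at the geometric mean of a group) and the percent of peaks within 1 kb of either end of a protein-coding gene (right, line at the mean) for the 3 groups, with 1 point per list numbered by replicate, circles for input pool 1 and squares for input pool 2. WT 0 h replicate 4 has 19960 peaks, and the 6 lists of input pool 2 all lie at 12.8% or above on the right, the 6 of pool 1 below that.

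The peaks merged into 24484 regions, of which 11945 (48.8%) were held by 1 list, 9310 of them by WT 0 h replicate 4. All 12 lists shared 181 regions, and 1922 were consensus regions of all 3 groups. The highest ranked region in each of the 3 groups lay inside Zbtb16, which codes for the zinc finger protein PLZF and responds to steroid hormones in many tissues (chromosome 9, 48722654 to 48725110). A region 12.2 kb from Piwil4, a PIWI family gene, also ranked among the first 5 in every group (chromosome 9, 14688340 to 14692344). Regions inside Klf13, a Krüppel-like transcription factor gene, and Cblb, which codes for a ubiquitin ligase, ranked among the first 5 at 6 h in both genotypes. Regions inside Tcf4 and Ncoa4, the latter coding for an AR coactivator, and 13.7 kb from Pdp1 ranked among the first 5 at 0 h. A region inside Foxp1 did so in WT 6 h and one 2.6 kb from Smarca1 in KO 6 h. Of 344 genes on the 21 gene lists, 20 had a summit within 50 kb in all 12 lists, among them the AR and glucocorticoid responsive genes Fkbp5, Per1, Klf9 and Zbtb16 and the follicle-stimulating hormone receptor gene Fshr. The 20 also held Gapdh, Gusb, Hprt and Ubc of the housekeeping control and Grin1 of the neuronal control, so they were not particular to AR responsive genes. The gene Ar itself had a summit within 50 kb in 0 of the 12 lists.

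The first comparison asks how AR binding differs after the ovulatory signal in wild-type cells. The strongest sites overlapped less between the 2 times than within either. The 1199 highest ranked peaks of a WT 6 h list overlapped those of a WT 0 h list by 29.6% ± 12.9 (SD, n = 16 pairs), against 74.3% ± 5.87 (SD, n = 6 pairs) within WT 0 h. Within WT 6 h the overlap was 45.3% ± 21.6 (SD, n = 6 pairs), and 64.6% ± 7.12 (SD, n = 3 pairs) without replicate 1, when that between the times was 35% ± 9.83 (SD, n = 12 pairs). WT 6 h replicate 2 shared the most with the WT 0 h lists, 43.4 to 50.8%. Overlap within the times exceeded overlap between them by 30.3 percentage points (one-sided exact permutation p = 0.0286, the smallest the 35 splits allow). Within input pool 1 the difference was 21.0 points and within input pool 2 it was 46.4 points. Of the 3628 consensus regions of WT 6 h, 62.0% (exact binomial 95% interval 60.4 to 63.6%, counting error only) were also consensus regions of WT 0 h, as were 26.5% of the 8490 of WT 0 h in the other direction. The first share was 37.4% with every list limited to 1199 peaks.

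**Figure D2:**
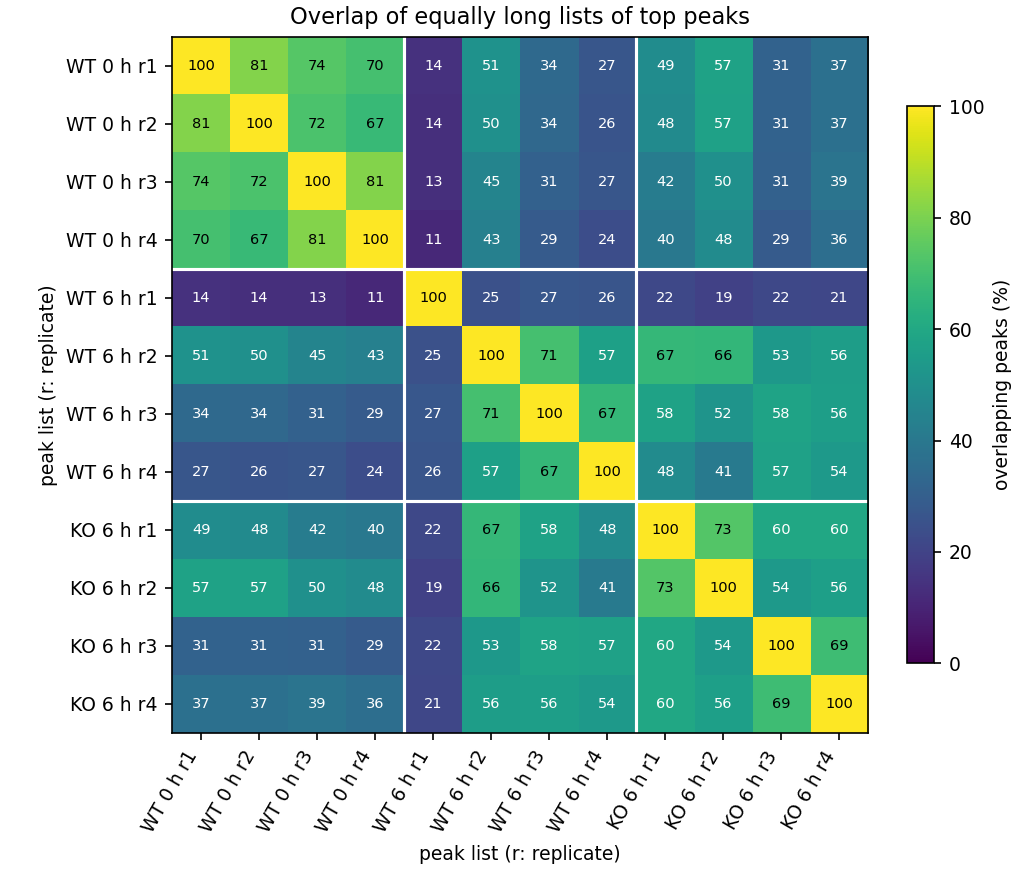
Overlap in percent between the 1199 highest ranked peaks of each pair of the 12 lists, ordered by group and replicate, with lighter cells for higher overlap. Pairs within WT 0 h share 74.3% on average and pairs of WT 0 h and WT 6 h lists 29.6%.

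Regions held by all 4 lists of one time and no list of the other numbered 53 for WT 6 h and 1327 for WT 0 h, 1380 together. No other split of the 8 lists gave more than 99. With every list limited to 1199 peaks, the numbers were 100 for WT 6 h and 248 for WT 0 h. The limit drops lower ranked peaks, so a region missing from a limited list may still lie in the full list. By Fisher's exact test, 1380 regions had an unadjusted p of 0.0286 and 0 passed the Benjamini-Hochberg adjustment, for which the smallest adjusted p was 0.492. Here and below, a count of 0 regions or genes after adjustment carries little information, since most of them would have to reach the smallest p. WT 6 h lists had 0.355 times as many peaks as WT 0 h lists by geometric mean, which did not exceed the spread between replicates (exact permutation p = 0.114), and 0.389 and 0.325 times within input pools 1 and 2. Without WT 6 h replicate 3 the ratio was 0.256 (exact permutation p = 0.0286). The median peak width was 296 bp ± 9.78 (SD, n = 4) in WT 6 h and 338 bp ± 33.8 (SD, n = 4) in WT 0 h (exact permutation p = 0.0286, adjusted p = 0.2 over 7 measures). The percent of peaks near gene ends was 13.2% ± 5.87 (SD, n = 4) in WT 6 h and 15.8% ± 11.6 (SD, n = 4) in WT 0 h (exact permutation p = 0.743), and the sign of this difference changed with every list limited to 1199 peaks (3.32 points).

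Among the regions held by all 4 WT 6 h lists and no WT 0 h list, one lay inside Smad3, which codes for a transducer of TGF-beta and activin signals (chromosome 9, 63743730 to 63744266), and one 22.4 kb from Socs2, a suppressor of cytokine signalling (chromosome 10, 95361291 to 95361879). The highest ranked of them lay inside Pde1a, which codes for a calcium-dependent phosphodiesterase (chromosome 2, 79945989 to 79946778). Others lay inside Wbp1l, Supt3, Bcas3 and Wdfy2 and within 50 kb of Gm815, Kcnv2 and Atp2b1. Those of Wbp1l and Wdfy2 were held by 0 KO 6 h lists, those of Socs2, Kcnv2 and Atp2b1 by 3 and the others named by 4. Regions at Fkbp5, which codes for a chaperone of steroid receptors and is a classical target of AR, differed among themselves. One inside it was held by 4 of 4 WT 0 h lists and 0 of 4 WT 6 h lists (chromosome 17, 28442082 to 28443131). A second inside it, chosen after its values were seen, had the same counts (28428298 to 28429282), and each was held by 1 KO 6 h list. Another 4 regions within 50 kb were held by all 12 lists. Further regions held by all 4 WT 0 h lists and no WT 6 h list lay inside Ogdhl and Nkain2, 0.6 kb from Ywhab, 10.9 kb from Ric1, and more than 100 kb from Adarb2, Slitrk6, Hace1, Magi1 and Sfrp2. KO 6 h lists held that of Adarb2 in 0, that of Ogdhl in 1 and the others in 2. With every list limited to 1199 peaks, all of the regions named by the rule but that of Hace1 kept 4 lists against 0.

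**Figure D3:**
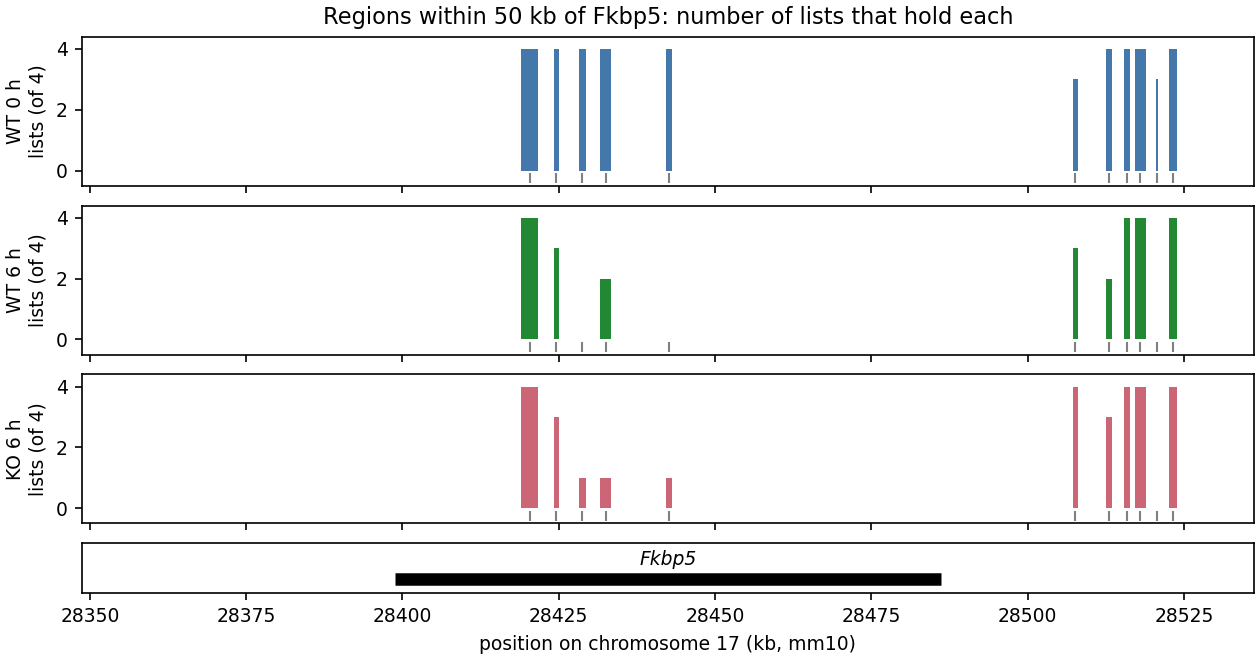
Map of the 11 regions within 50 kb of Fkbp5 on chromosome 17 (mm10 position on the x axis, ticks at the regions) that at least 3 of the 12 lists held, with bars for the number of lists out of 4 in each group. The region from 28442082 to 28443131 is held by 4 WT 0 h lists, 0 WT 6 h lists and 1 KO 6 h list.

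Of the 344 genes on the gene lists, 7 had a summit within 50 kb in all 4 WT 0 h lists and no WT 6 h list, and 0 the reverse. By Fisher's exact test those 7 had an unadjusted p of 0.0286 and 0 passed the adjustment over the 344 genes (smallest adjusted p 1). They included Il6 and Ptgs2, which code for a cytokine and the prostaglandin synthase that act in ovulation. The others were Amhr2, the receptor gene for anti-Müllerian hormone, the transcription factor genes Cebpd and Myc, Herpud1, and Sdha of the housekeeping control list. The lists of WT 0 h were longer, and 204 genes were near peaks in more WT 0 h lists against 34 in more WT 6 h lists. With every list limited to 1199 peaks, none of these 7 genes kept 4 lists against 0. Among those highest ranked peaks, 5 genes had 4 WT 6 h lists and no WT 0 h list (Adamts9, Cd14, Epas1, Prkg2 and Zar1, chosen after their values were seen) and 1 the reverse (Map2). On full lists Adamts9, Cd14 and Epas1 were near summits in 4 WT 0 h lists, Prkg2 in 2 and Zar1 in 1, and Map2 in 1 WT 6 h list, so the limit shows lower ranked peaks and no absence of them. The number found on full lists at 0 h and not at 6 h was 21 without WT 6 h replicate 3 and 12 without WT 0 h replicate 3. With a list left out the rule is easier to meet, so this number can hardly fall.

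Of the genes named one by one, some had nearby AR peaks in fewer lists at 6 h and some in more. The steroid enzyme gene Cyp17a1, also a marker of theca cells, the forkhead gene Foxo1, the inhibin subunit gene Inhbb and Nr5a1, which codes for the regulator of steroidogenesis SF-1, each had a summit within 50 kb in 4 WT 0 h lists and 1 WT 6 h list. Foxl2, needed for granulosa cell identity, had one in 3 WT 0 h lists and 0 WT 6 h lists. In the other direction, the immediate early gene Egr3 was near a summit in 1 WT 0 h list and 4 WT 6 h lists. The syndecan gene Sdc1 was near one in 0 and 3, and Runx2, which codes for a RUNX transcription factor of the ovulatory follicle, in 1 and 3. The clock gene Rora had 1 and 3, which changed direction within 100 kb, and Prkg2, a kinase gene that depends on PGR, had 2 and 4. Runx1 had 2 and 3 lists and Pgr had 1 and 2. These counts were not corrected for list length, and none of the genes in this paragraph differed by 4 lists against 0. The gene lists of follicle growth (log2 ratio 1.09 ± 0.52 in WT 6 h and 0.97 ± 0.55 in WT 0 h, SD, n = 4, exact permutation p = 0.714) and steroidogenesis (1.35 ± 0.30 and 1.10 ± 0.48, SD, n = 4, exact permutation p = 0.429) differed between the times by less than the spread between lists.

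**Figure D4:**
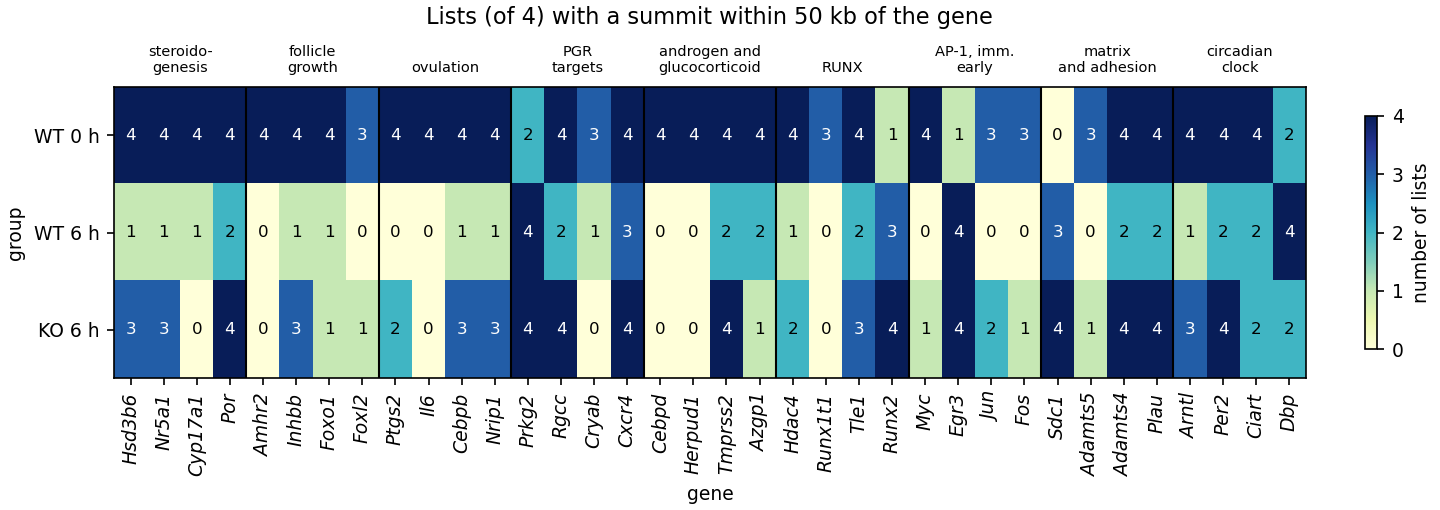
Number of lists out of 4 with a summit within 50 kb of 36 genes from 9 of the gene lists, for WT 0 h, WT 6 h and KO 6 h. Il6, Cebpd and Herpud1 have 4, 0 and 0 lists, and Egr3 has 1, 4 and 4.

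None of the 21 gene lists differed between WT 6 h and WT 0 h (exact permutation test, 0 lists at an adjusted p of 0.05, 2 at an unadjusted p under 0.05, smallest adjusted p 0.171). Those 2 were the circadian clock genes, whose log2 ratio to all protein-coding genes was 1.41 ± 0.72 (SD, n = 4) in WT 6 h and 0.35 ± 0.19 (SD, n = 4) in WT 0 h, and the oocyte markers, with 0.11 ± 0.44 (SD, n = 4) and −0.46 ± 0.20 (SD, n = 4, exact permutation p = 0.0286 for each list). The log2 ratio was higher in WT 6 h than in WT 0 h for 20 of the 21 lists. The housekeeping control was among them (1.30 ± 0.61 and 0.77 ± 0.33, SD, n = 4), so a higher ratio was not particular to those 2 lists. The mean share of circadian clock genes near peaks was lower in WT 6 h, 42.6% against 52.9%. For oocyte markers it was 17.3% against 28.8%. The smallest adjusted p this design can give reaches 0.05 only if at least 12 lists reach the smallest p.

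The second comparison asks how AR binding 6 h after hCG depends on PGR. Few AR regions set the genotypes apart, and whether more than chance depended on list length. On full lists other groupings of the same 8 lists gave as many, while with every list limited to 1199 peaks the genotypes gave 49 such regions and no other grouping more than 38. The highest ranked peaks of a KO 6 h list overlapped those of a WT 6 h list by 46.9% ± 16.5 (SD, n = 16 pairs), and by 55.5% ± 7.02 (SD, n = 12 pairs) without WT 6 h replicate 1. Overlap within KO 6 h was 62.0% ± 7.45 (SD, n = 6 pairs). Overlap within the genotypes exceeded overlap between them by 6.82 percentage points (one-sided exact permutation p = 0.0286, the smallest the 35 splits allow), and by 5.64 and 11.3 points within input pools 1 and 2. Leaving out any of the lists except WT 6 h replicate 2 ended this call, as did full lists, reciprocal overlap and the Jaccard index. Without KO 6 h replicates 1 to 4 the difference was 3.86, 3.49, 4.66 and 4.13 points, and without WT 6 h replicates 1, 3 and 4 it was 7.40, 9.46 and 9.20 points (exact permutation p between 0.0571 and 0.286). Of the 4347 consensus regions of KO 6 h, 62.6% (exact binomial 95% interval 61.2 to 64.1%) were consensus regions of WT 6 h, as were 75.1% of those of WT 6 h in the other direction. Without WT 6 h replicate 3 the first share was 28.4%, and without WT 6 h replicate 2 it was 32.4%.

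Regions held by all 4 lists of one genotype and no list of the other numbered 15 for KO 6 h and 13 for WT 6 h, 28 together, and 9 of the 35 splits of the 8 lists gave as many. The count was 55 without KO 6 h replicate 1, 68 without KO 6 h replicate 4, 121 without WT 6 h replicate 1 and 124 without WT 6 h replicate 3. Leaving out a list eases the rule, so a count can hardly fall and a rise alone does not mark that replicate. By Fisher's exact test the 28 had an unadjusted p of 0.0286 and 0 passed the adjustment (smallest adjusted p 1). With every list limited to 1199 peaks there were 19 for KO 6 h and 30 for WT 6 h, where absence again means only absence from the highest ranked peaks. KO 6 h lists had 1.45 times as many peaks as WT 6 h lists by geometric mean (exact permutation p = 0.429), 2.19 times within input pool 1 and 0.958 times within input pool 2. The percent of peaks near gene ends was 15.3% ± 9.67 (SD, n = 4) in KO 6 h, 2.04 points above WT 6 h (exact permutation p = 0.8), and the difference was −2.44 points within input pool 1.

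The regions held by all 4 WT 6 h lists and no KO 6 h list included one each inside Epas1, which codes for the hypoxia factor HIF-2 alpha (chromosome 17, 86798929 to 86799428), and Adamts9, which codes for a matrix protease (chromosome 6, 92787527 to 92787872), both genes of the ovulatory response. A second region inside Adamts9 was held by all 12 lists and a second inside Epas1 by 4 KO 6 h lists, 3 WT 6 h lists and 4 WT 0 h lists. Others lay inside S100a10, Nek7, Wbp1l and Wdfy2 and 6.1 kb from F2r, which codes for a thrombin receptor. The rest lay 8.6 kb from Fignl2, 1.4 kb from Slc25a33 and 43.4 kb from Lpgat1. Of these 13 regions, 10 were held by no WT 0 h list and 0 by 2 or more. Those named, except that near Fignl2, kept 4 lists against 0 with every list limited to 1199 peaks. The regions held by all 4 KO 6 h lists and no WT 6 h list included a weaker one inside Cblb (chromosome 16, 52075805 to 52076108) and one 5.7 kb from Prkar2b, which codes for a regulatory subunit of protein kinase A (chromosome 12, 32066815 to 32067751). Others lay inside Astn2, Abca4 and Brinp3, 0.7 kb from Emilin2 and 31.9 kb from Ado, and more than 100 kb from Lacc1, Mettl4 and Adam28. Of these 15 regions, 6 were held by 2 or more WT 0 h lists, 4 of them by all 4. With every list limited to 1199 peaks, none of the 10 named kept 4 lists against 0.

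Of the 344 genes, 1 was near a summit in all 4 KO 6 h lists and no WT 6 h list, the immediate early gene Egr2, and 0 the reverse. Egr2 had an unadjusted p of 0.0286 by Fisher's exact test and 0 genes passed the adjustment (smallest adjusted p 1). Without WT 6 h replicate 3, which makes the rule easier to meet, there were 6 such genes. More genes were near peaks in more KO 6 h lists, 124, than in more WT 6 h lists, 52. With every list limited to 1199 peaks there were 0 for KO 6 h and 1 for WT 6 h, Cd14, which 2 full KO 6 h lists held, and Egr2 no longer differed. Genes of the ovulatory response also had nearby AR peaks without PGR. The protease gene Adamts4 and the gene Rgcc had 2 WT 6 h lists and 4 KO 6 h lists. Btc, which codes for the growth factor betacellulin, had 0 and 3, and the endothelin gene Edn2 had 1 and 3, which changed direction with every list limited to 1199 peaks. The immediate early genes Klf6 and Ier3 and the vascular peptide gene Adm had 1 and 4, with the direction at Ier3 changed within 10 kb. Runx1 had 3 and 4, and the clock gene Dbp went the other way with 4 and 2. At Pgr, a region 31.2 kb away was held by 2 WT 6 h lists and 4 KO 6 h lists (chromosome 9, 8867536 to 8868002) and one 30.1 kb away by 1 and 4 (chromosome 9, 8868512 to 8869081). These are AR peaks near the gene and no measure of its expression.

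None of the 21 gene lists differed between KO 6 h and WT 6 h (exact permutation test, 0 lists at an adjusted p of 0.05, 0 at an unadjusted p under 0.05, smallest adjusted p 0.938). For the genes reported as lower without PGR, the log2 ratio was 1.41 ± 0.44 (SD, n = 4) in KO 6 h and 1.63 ± 0.51 (SD, n = 4) in WT 6 h (exact permutation p = 0.543), and the sign of the difference changed with every list limited to 1199 peaks.

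The regions that set the 2 times apart in wild-type cells were also read in the knockout lists. Of the 53 regions in all 4 WT 6 h lists and no WT 0 h list, 39 (73.6%) were held by 2 or more KO 6 h lists, 23 of them by all 4, and 10 by none. Of the 1327 regions in all 4 WT 0 h lists and no WT 6 h list, 119 (8.97%) were held by 2 or more KO 6 h lists. Another 664 were held by 1 KO 6 h list and 544 by none. Of the 207 regions in all 8 wild-type lists, 204 (98.6%) were held by 2 or more KO 6 h lists. The regions were chosen on the wild-type lists, so these shares describe the knockout lists and test no difference between genotypes.

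Genes of follicle function lay near AR consensus regions in every group, more often than protein-coding genes as a whole, of which 43.2%, 20.1% and 25.8% did in WT 0 h, WT 6 h and KO 6 h. In each group 10 of the 21 gene lists passed an adjusted p of 0.05 by a one-sided Fisher's exact test. Of the 24 steroidogenesis genes, 83.3% in WT 0 h (adjusted exact p = 0.00138), 62.5% in WT 6 h (adjusted exact p = 0.000149) and 66.7% in KO 6 h (adjusted exact p = 0.000293) lay near a consensus region. For the 20 genes reported as lower without PGR the shares were 80%, 60% and 70% (adjusted exact p = 0.00624, 0.000752 and 0.000293), and for the 32 ovulation genes 65.6%, 53.1% and 65.6% (adjusted exact p = 0.0255, 0.000368 and 5.12e-05). Follicle growth genes (75.0%, 54.2% and 54.2%), androgen and glucocorticoid response genes (70.8%, 54.2% and 50%), coregulators (68.2%, 45.5% and 54.5%) and matrix and adhesion genes (65.4%, 50% and 46.2%) also passed in all 3 groups, with adjusted exact p between 0.000963 and 0.0454. Genes linked to androgen action in granulosa cells passed in WT 0 h (81.2%) and WT 6 h (50%) but not in KO 6 h (50%, adjusted exact p = 0.0562). AP-1 and immediate early genes passed in WT 0 h (69.6%) and KO 6 h (60.9%) but not in WT 6 h (39.1%, adjusted exact p = 0.0541). The circadian clock passed in WT 6 h (52.9%) and KO 6 h (58.8%) but not in WT 0 h (52.9%, adjusted exact p = 0.398). RUNX genes passed in KO 6 h (60%) but not in WT 0 h (70%, adjusted exact p = 0.156) or WT 6 h (50%, adjusted exact p = 0.0543). Angiogenesis and hypoxia genes passed in WT 6 h (44.4%) and not in WT 0 h (50%) or KO 6 h (44.4%). The housekeeping control passed in WT 0 h (87.5%, adjusted exact p = 0.00354), so a pass at 0 h is not particular to granulosa cell genes. It did not pass in WT 6 h (31.2%, adjusted exact p = 0.288) or KO 6 h (50%, adjusted exact p = 0.0562). In KO 6 h its share and adjusted p equalled those of the genes linked to androgen action in granulosa cells. Its mean log2 ratio per list in WT 6 h was 1.30 ± 0.61, against 1.35 ± 0.30 for steroidogenesis genes (SD, n = 4). These differences between groups in what passed were not tested as such.

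Nuclear receptor genes (50%, 33.3% and 33.3% in WT 0 h, WT 6 h and KO 6 h), cell cycle genes (60%, 40% and 40%), Hippo pathway genes (66.7%, 8.33% and 33.3%) and the neuronal control (50%, 21.4% and 35.7%) passed in no group. The marker lists of theca and stroma (35.7%, 14.3% and 21.4%), immune cells (50%, 25% and 33.3%), endothelium (16.7%, 25% and 16.7%) and oocytes (30.8%, 15.4% and 30.8%) also passed in none by the same test, at an unadjusted p of 0.0332 for the cell cycle genes in WT 6 h and no other under 0.05. Against random lists matched on gene length, 8 of the 10 lists held in WT 0 h, 7 in WT 6 h and 6 in KO 6 h. Coregulators were lost in all 3 groups (length-matched adjusted permutation p = 0.15, 0.0707 and 0.0586 in WT 0 h, WT 6 h and KO 6 h), and matrix and adhesion genes in WT 0 h (permutation p = 0.14) and KO 6 h (permutation p = 0.106). Genes linked to androgen action in granulosa cells and angiogenesis genes were lost in WT 6 h (permutation p = 0.0504 each). Androgen and glucocorticoid response genes (permutation p = 0.0555) and RUNX genes (permutation p = 0.137) were lost in KO 6 h. The AP-1 and immediate early genes passed only this test in WT 6 h (permutation p = 0.0307). Within 50 kb of either gene end, chosen after seeing the data, 13 lists passed in WT 6 h and 9 in each other group. Cell cycle, AP-1 and RUNX genes then passed in WT 6 h (adjusted exact p = 0.0445, 0.0409 and 0.0447), and matrix and adhesion genes were lost in WT 0 h and KO 6 h (adjusted exact p = 0.0763 and 0.0713). At equal list length 2, 3 and 6 lists passed, and without WT 0 h replicate 3 or replicate 4 the number in WT 0 h was 3.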

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

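The tests of shorter lists at 6 h, the input pool in the first pattern, treatment in either genotype, lower yield, swapped labels, crowded peaks in the 6 lists, arrangements of the input pools, pairs of lists and the pools without WT 6 h replicate 1 below were chosen only after the result was seen.

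A search for a list far from the other 3 of its group covered 10 measures in 3 groups, 30 sets, of which chance alone gives about 1 in 20, and found 5. WT 0 h replicate 4 accounted for 4 of them: it had 19960 peaks (the others 5083 to 6499), a median width of 388 bp (315 to 325), 53.4% of its peaks in any other list (97.9 to 99.2%) and 42.6% in another WT 0 h list (96.4 to 98.9%). WT 6 h replicate 1 had 58 peaks on contigs outside the chromosomes (0 to 3 in the others).

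The first pattern weighed is that WT 6 h and WT 0 h lists held different regions. Only 1 of the 35 splits of the 8 lists, the real one, gave as many as 1380 in all 4 lists of one side and none of the other (highest other 99). That share, 0.0286, is under the 0.05 set beforehand, which argues against chance. It is also the smallest the splits allow, so chance is not excluded. At equal list length the real split gave 348 (highest other 14), which argues against shorter lists at 6 h as the whole cause. The input pool cannot account for it within pool 2, where overlap was 27.5% between the times against 81.4% within WT 0 h and 66.5% within WT 6 h. Pool 1 shows less: without WT 6 h replicate 1 the overlap was 50.5% between the times against 81.4% within WT 0 h, but 1 list is then left at 6 h, and with that replicate the overlap within WT 6 h was 25.0%. An effect of hCG in either genotype predicts KO 6 h lists closer to WT 6 h than to WT 0 h, which held for 3 of 4, while KO 6 h replicate 2 had a median overlap of 46.2% with WT 6 h and 53.8% with WT 0 h. A change of AR sites after hCG stays open as a hypothesis, since depth and the quality of each library, which are unknown, may also set which sites reached a list.

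The second pattern is that WT 6 h replicate 1, the shortest list, stood apart. Of its peaks 40.4% lay in the longest WT 6 h list, below the 55.4% of the lowest other list, which a lower yield of the same sites would not give, and its median overlap was 26.2% with the other WT 6 h lists against 21.5% with KO 6 h and 13.5% with WT 0 h, which a swapped label would not give. A test written beforehand, of enriched segments that crowd its 601 unshared peaks, gave 20.3% within 1 Mb of another against 30.8% in the highest other list, but that list had 13 such peaks (interval 9.09 to 61.4%), so it settles nothing. Among the 6 lists with at least 100 unshared peaks and 131 drawn from each, it had 45.5% against at most 20%, and chromosome 8 held 12.5% of its peaks (at most 5.38% in the others), which is consistent with broad enriched segments in this library. No biological explanation was tested, and what made such segments stays open.

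The third pattern is that the 6 lists of input pool 2 had 22.1% ± 5.09 (SD) of peaks within 1 kb of a gene end against 7.5% ± 2.72 in the 6 of pool 1, a difference of 14.6 points that 2 of 216 exchanges within groups matched (two-sided exact permutation p = 0.00926, highest other 14.3), but every pool 2 list had by then been seen above every pool 1 list, so this p does not exclude chance. A test written beforehand took list length as the cause if p rose above 0.05 at equal length. With 1199 peaks per list the difference was 3.76 points (exact permutation p = 0.12, highest other 3.66), so this test went with length. It rests on WT 6 h replicate 1, at 12% against 2.92 to 3.42% in the other 5 lists of pool 1 and 5 to 13.8% in pool 2. Without that list the difference was 5.24 points (exact permutation p = 0.0185, highest other 4.70, also with the values in view). On full lists KO 6 h replicate 4, with 2878 peaks, had 24% against 4.82% in KO 6 h replicate 1, with 3198. These values, chosen after being seen, argue against length as the whole cause but do not exclude it. In 14 of 14 pairs of a pool 1 list and a shorter pool 2 list the pool 2 list had the higher percent, but this followed from the separation of the pools and is no further test. The input pool with everything else that went with it stays open, as does list length, and no biological explanation was tested, since each group has 2 lists in each pool.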

How the results depend on the processing

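Tests at −log10 p of at least 20, within 50 kb of either gene end, at equal length within pools or without WT 6 h replicate 1, against length-matched lists, and of the gene-end share itself were chosen after seeing the data. No result past its threshold changed direction, but several others did, as given below. The planned q of at most 1e-05 removed 0 peaks and is void. Motif tests, their other windows and promoter windows were not run, for want of sequence and strand. Where no construction is named, the cause was not tested.

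For WT 6 h against WT 0 h, the overlap difference of 30.3 points stayed past its threshold in the alternatives other than those with fewer arrangements: with replicate block (30.3, exact p = 0.125) or exchange within pools (30.3, exact p = 0.0556), and in pool 1 (21.0) and pool 2 (46.4) alone, the design cannot reach 0.05. The peak ratio ranged from 0.256 to 0.482 with 1 list left out, past the threshold without WT 6 h replicate 3 (0.256). The 1380 regions in all lists of one side became 348 at equal length (also exchanged within pools), 549 at equal length without WT 6 h replicate 1, 2869 with at least 3 lists, and 2335 and 3932 in pools 1 and 2, where 2 lists per side suffice. With 1 list left out they ranged from 1393 to 1955. Leaving out a list eases the rule, so such counts, here and for KO 6 h against WT 6 h below, can hardly fall. The share of WT 6 h consensus regions found at 0 h, 62.0%, became 52.6%, 59.8% and 60.2% with 3, 4 or any lists required, 59.1% at −log10 p of at least 20, 37.4% at equal length, 42.4% with reciprocal overlap of 50% and 50.2 to 63.6% with 1 list left out.

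For KO 6 h against WT 6 h, the overlap difference of 6.82 points was not past the threshold with reciprocal overlap (5.55), full lists (4.90), Jaccard index (4.31), replicate block (6.82, exact p = 0.125), exchange within pools (6.82, exact p = 0.0556) or in pool 1 (5.64) or 2 (11.3), and ranged from 3.49 to 12.3 with 1 list left out. The 28 regions became 49 at equal length (also exchanged within pools), where the real split exceeded all others (highest 38, the split by input pool), 114 without WT 6 h replicate 1 at equal length, 199 with at least 3 lists, 643 and 359 in pools 1 and 2, and 32 to 124 with 1 list left out. On full lists 9 of 35 splits gave 28 or more, so chance is not excluded; the highest, 283, set KO 6 h replicates 1 and 2 with WT 6 h replicates 2 and 3, which points to a structure of the lists other than genotype. The consensus share of 62.6% became 42.2% and 17% with 3 or 4 lists required, 58.1% at equal length, 59.6% with reciprocal overlap and 28.4 to 72.7% with 1 list left out.

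Of the 10 gene lists enriched in WT 0 h, the count was 5 within 10 kb, 3 with 3 lists required, 2 at equal length, 3 at −log10 p of at least 20, and 3 to 10 with 1 list left out (3 without replicate 3 or 4). The 10 in WT 6 h became 13 within 50 kb of either end, with cell cycle, AP-1 and RUNX genes added (adjusted exact p = 0.0445, 0.0409 and 0.0447), 3 at equal length, 6 at −log10 p of at least 20 and 8 to 10 with 1 left out, and the 10 in KO 6 h became 6 at equal length, 6 against length-matched lists and 9 to 12. Within 50 kb of either end 9 passed in WT 0 h and 9 in KO 6 h, both without matrix and adhesion genes (adjusted exact p = 0.0763 and 0.0713). The gene-end share and the count of 0 differing gene lists never passed their thresholds in the alternatives run, but signs changed. The gene-end difference between WT 6 h and WT 0 h, −2.56 points, was 3.32 at equal length, 3.61 in pool 1 and −6.03 to 1.56 with 1 list left out (1.56 without WT 0 h replicate 4). That between KO 6 h and WT 6 h, 2.04 points, was −2.44 in pool 1 and −0.864 to 5.53 with 1 list left out (below 0 without KO 6 h replicates 3 or 4 or WT 6 h replicate 2). The KO 6 h to WT 6 h peak ratio of 1.45 was 0.958 in pool 2. The difference of genes lower without PGR was 0.0381 on the log2 scale at equal length. Of 378 gene list differences per comparison, 21 changed sign for WT 6 h against WT 0 h and 67 for KO 6 h against WT 6 h, with adjusted exact p of 0.15 and 0.88 or above. Among genes on the lists, found in all 4 lists at 0 h and none at 6 h or the reverse, 7 and 0 became 1 and 5 at equal length, through peaks ranked below the limit, and for KO 6 h against WT 6 h 1 and 0 became 0 and 1. Of 8 genes and 40 regions named as differing, counted once per comparison, with those of Wbp1l and Wdfy2 in both, 8 and 12 no longer did at equal length and 4 and 9 at −log10 p of at least 20. Genes that did not pass also changed direction in their number of lists. For WT 6 h minus WT 0 h at equal length, Angpt2, Axl, Bnip3, Cbfa2t3, Ciart and Tle1 came to 1, Nr4a1 and Top2a to 2 and Lox to 3. Within 10 kb, Adamts4, Adm and Syt1 came to 1, Ncoa1 to 3, Cdkn1b to −1 and Tef to −2, and within 100 kb Rora to −1. For KO 6 h minus WT 6 h, Axl, Bhlhe40, Bnip3, Cdk6, Col4a2 and Edn2 came to −1 at equal length and Tle1 to −1 at −log10 p of at least 20. Within 10 kb, Hmbs, Ier3 and Syt1 came to −1 and Bnip3 and Vcan to −2, and Rora to −1 within 50 kb of either end.

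Replicate numbers were tested as pairs before use: across regions, the correlation of same-number lists ranged from −0.0214 to 0.214 for WT 6 h and WT 0 h and from −0.0399 to 0.263 for KO 6 h and WT 6 h, so not every pair reached the 0.1 set for taking numbers as pairs, and they were not so taken. In each comparison 3 of 4 lists correlated best with the list of their own number, a hint from the data and not the design. Lists of one input pool correlated at 0.0572 and 0.129 on average, lists of different pools at −0.0570 and −0.129. Depth was unknown, and a list's length limits which sites it can show.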

Other observations

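The tests of KO 6 h against WT 0 h were chosen only after the data were seen.

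Knockout lists at 6 h and wild-type lists at 0 h differ in both genotype and time, so no cause can be read from them. Overlap of the highest ranked peaks was 41.4% ± 9.22 (SD, n = 16 pairs) between these groups, 26.8 points below the overlap within them (one-sided exact permutation p = 0.0286). Regions in all 4 KO 6 h lists and no WT 0 h list numbered 307, and 602 were found the other way, 909 together. Of the 35 splits only the real one gave as many (highest other 306), the smallest share the splits allow. By Fisher's exact test 0 regions passed the adjustment (smallest adjusted p 0.704). The counts were in view when this test was chosen, so it does not exclude chance. At equal list length the numbers were 167 and 172. Of the 4347 consensus regions of KO 6 h, 64.5% were consensus regions of WT 0 h. KO 6 h lists had 0.515 times as many peaks (two-sided exact permutation p = 0.114).

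A hypothesis from the overlap values was that cells without PGR may keep more of the 0 h sites at 6 h. KO 6 h lists overlapped WT 0 h lists by 41.4% ± 9.77 (SD, n = 4) and WT 6 h lists did by 29.6% ± 14.2 (SD, n = 4), a difference of 11.8 points (two-sided exact permutation p = 0.229, within input pools p = 0.222) that does not exceed the spread between lists. Without WT 6 h replicate 1 the second value was 35%.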
